A study of Arabidopsis thaliana with 16 samples.

How the data were processed

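The series measured polyadenylated RNA of Arabidopsis thaliana seedlings by sequencing in 16 libraries, 4 for each of 4 groups. Per the labels, wild-type seedlings and a homozygous line carrying ATML1pro:GR-SPCH1-4A-YFP were kept cold for 2 days as seeds, germinated in liquid Murashige and Skoog medium with 1% sucrose, and shaken at 90 rpm until 7 days after germination. In this transgene the epidermal ATML1 promoter drives SPEECHLESS (SPCH), in a variant with altered phosphorylation sites, fused to the glucocorticoid receptor (GR) domain and a yellow fluorescent protein. The fusion enters the nucleus when dexamethasone is bound. Seedlings were collected at 0 h without treatment and at 12 h after 100 μM dexamethasone. No group at 12 h without dexamethasone was analysed here, so that in each line dexamethasone and elapsed time changed together, and the labels give no time of day. Per the labels, RNA was extracted with an RNeasy Micro kit, libraries were made with an Illumina TruSeq poly-A kit, and replicates 1 and 2 of every group shared 1 sequencing lane while replicates 3 and 4 shared a second.

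The deposited table held 33602 genes by locus identifier and 16 columns, 1 per library, each matched to its library by its name. The submitters' processing notes name TopHat, SAMtools, HTSeq and DESeq2 and the TAIR10 build, without versions. The annotation release, the strand setting of the counting and the handling of reads with several alignments are not given in the sources used here. The values were a signal, the number of reads per gene that the authors had divided by 1 size factor per library. This was read from the values: in each column 100% of the deposited values lay within 0.001 read of a whole multiple of 1 step, and the steps equalled the inverse of median-of-ratios factors computed from the recovered reads. The recovered totals ranged from 16251477 to 22944391 reads per library, and 3 reads, the upper limit that a count of 0 allows, were at most 1.8e-05% of a library. Limits of this kind cover counting error only. The matching of the table to RefSeq gene models of TAIR10.1 covered 32835 of the 33602 genes and supplied symbols, products and positions. Nuclear positions are given from that annotation, counted from 1.

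The test fixed before the data were examined was edgeR's quasi-likelihood test, which needs raw counts. Since the deposited values were normalized, limma 3.58.1 in R 4.3.3 was used in its place as the main test, on log2(normalized count + 1), with an intensity trend and robust empirical Bayes moderation. The 20756 genes with at least 10 normalized counts in at least 4 libraries were tested, all 16 libraries entered 1 fit of the 4 group means without a further term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes and folds are on this scale with its pseudocount of 1, which understates the change of genes with low counts. Levels are normalized counts as mean ± SD over 4 libraries. The edgeR test (version 4.0.16, TMM factors) was run on the recovered reads as an added alternative, once 100% of values had come out whole. It used the 20756 genes above in place of edgeR's own filter, which the plan had named. It called 107 genes in the interaction, 1067 in the inducible line over time, 978 in wild type over time, 685 between the lines at 12 h and 411 between the lines at 0 h.

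The comparisons were the change from 0 to 12 h in the inducible line, the same change in wild type, the lines against each other at 12 h and at 0 h, and the line-by-time interaction, which is the 12 h change of the inducible line minus that of wild type. An induction set was defined as the genes past the threshold with the same sign in both the interaction and the comparison at 12 h. These share the 12 h libraries, so the set is a definition and not separate evidence. The labels do not say that the 4 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be partly technical.

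The genes named follow a rule fixed before the data were examined. It took SPCH and PIF4 always and, in the interaction, the 10 largest rises and 10 largest falls past the threshold. These also needed a mean of at least 1 log2 CPM (TMM factors), with the 12 h libraries of the lines not overlapping. In each other comparison it took the 6 largest rises and 6 largest falls by the same rule, with no overlap between the groups compared. From each gene list it took up to 4 members with the smallest adjusted p, and from the stomatal lineage list any member. Genes outside that rule are named as chosen after their values were seen. The results below do not name every gene that the rule took. Left out there are, among others, the largest falls of the interaction, AT5G04120 (log2 -2.74, adjusted p = 0.039) and CPK22 (-2.45, adjusted p = 0.049). The 23 gene lists were also fixed beforehand: stomatal lineage factors, stomatal signalling upstream of SPCH, guard cells, mitosis, DNA replication, D-type cyclins and CDK inhibitors, PIF4 and warm temperature, circadian clock, brassinosteroid, auxin response, abscisic acid and drought, jasmonate and wounding, defence and salicylate, low oxygen, darkness and sugar starvation, photosynthesis, epidermis and cuticle, trichomes, root hairs and root epidermis, vascular tissue, root endodermis, shoot meristem and leaf primordia, and seed storage. Of 420 list entries 5 were not matched, 9 repeated a locus of their list and 14 were resolved by product name. Lists were tested with limma's camera, 2-sided, with a preset correlation between genes of 0.01 and adjustment over the 23 lists of a comparison. The same test with a correlation estimated from the data is given beside a list's call. The number of members past the threshold is given over all tested genes and adjusted over the list alone.

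Replicate numbers paired the libraries, because the labels tie them to the sequencing lanes. After subtraction of group means, all 24 pairs of libraries with the same number correlated across genes, with r from 0.52 to 0.72. Pairs in the same lane with different numbers gave 0.53 to 0.76, pairs in different lanes gave -0.75 to -0.53, all 16 libraries correlated best with a library of their own lane, and 6 of 16 with their own number. The libraries thus matched by lane, with no closer match by number within a lane. The fit with the replicate number as a block takes up the lane difference. It is therefore given beside the printed calls it changed and the printed counts it moved by over 1.5 times. The design is balanced over lanes, so the block left every fold change as it was and altered its error. No pair of libraries held identical values, and all replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom from 10.4 to 40.0 within a lane and from 24.4 to 67.4 between lanes. The largest value within a lane belonged to wild-type 0 h replicates 1 and 2.

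Both steps were tested on simulated data. Counts for 20637 genes were drawn from the means, spreads, lane differences and sizes of these libraries, with genes raised or lowered in the inducible line at 12 h. The changed genes were picked above a higher minimum of counts than the filter of the test. Their recovery therefore does not cover genes with the lowest counts. In the simulated interaction, 36 of 100 genes changed by 1 on the log2 scale and 85 of 100 changed by 2 were recovered with no false call. With the replicate block these were 68 and 96, with 5 false calls. In the simulated comparison of lines at 12 h 68 and 97 of 100 were recovered with 1 false call, and in that of the inducible line over time 67 and 96 with 5 false calls. In a simulated interaction with 1 raised list, that list was called and 0 of the other 22 were. The counts were drawn gene by gene and these other lists held random genes. The simulation therefore says nothing of false calls in lists whose members correlate.

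Alternatives were edgeR with DESeq2-type (RLE) and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, a lane term, the replicate block, each library left out in turn, each lane alone, the compared groups alone, and stricter thresholds. The list tests were repeated with estimated correlation, fry, the block and left-out libraries. The planned RLE scaling of the list tests was the scaling of the deposited values itself, so TMM was run instead. Added after the data were seen were edgeR with TMM and its own filter or the block, other pseudocounts, TMM factors under limma, list tests in each lane alone and with both the block and estimated correlation, and the omission of genes covered by a gene on the opposite strand. A 2-sided exact permutation test was run for SPCH and PIF4, on normalized counts rather than the planned CPM. With 4 libraries against 4 its smallest possible p is 0.0286. No library was left out of the main results. A planned test of the lane difference against exon length is not reported here.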

Results

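Messenger RNA was measured in whole Arabidopsis seedlings 7 days after germination, in 16 libraries that fall into 4 groups of 4: a line with a dexamethasone-inducible form of the transcription factor SPEECHLESS (SPCH), called the inducible line here, and wild type, each at 0 h and at 12 h after dexamethasone. The total reads assigned to genes ranged from 16876720 to 19741388 in the inducible line at 0 h, from 18421440 to 20456141 at 12 h, from 16590689 to 22944391 in wild type at 0 h and from 16251477 to 18888133 at 12 h. Values below are normalized read counts, n = 4 libraries per group, and adjusted p-values are those of limma with the Benjamini-Hochberg method unless another tool is named.

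SPCH, the factor that starts the stomatal lineage, lies on chromosome 5 from 21586219 to 21589255 (AT5G53210, TAIR10 coordinates). Its transcript, to which reads of the transgene also count, stood at 140 ± 16.2 (SD, n = 4) in the inducible line and 63.4 ± 6.26 in wild type before treatment. It was 2.18-fold higher in the inducible line at 0 h (log2 difference 1.12, SE 0.15, adjusted p = 0.0020) and 2.99-fold higher at 12 h (1.58, SE 0.15, adjusted p = 1.1e-05), when the means were 200 ± 31.6 and 65.7 ± 5.73. The difference at 0 h had an adjusted p of 0.263 in lane 1 alone. Over the 12 h the log2 change was 0.51 in the inducible line (adjusted p = 0.064) and 0.05 in wild type (adjusted p = 0.90), and the difference of these changes was 0.46 (SE 0.21, adjusted p = 0.43). The change in the inducible line had an adjusted p of 0.051 with the replicate block, 0.037 with a lane term and 0.020 in DESeq2. The 2-sided exact permutation p was 0.0286, the smallest possible, for both comparisons of lines and for the change in the inducible line, and 0.60 for the change in wild type.

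PIF4, a growth regulator of warm-temperature responses that the series title names beside SPCH, lies on chromosome 2 from 17886101 to 17889087 (AT2G43010). At 12 h it was lower in the inducible line, with a log2 difference of -0.71 (SE 0.19, adjusted p = 0.042, exact permutation p = 0.0286), and at 0 h the difference was 0.21 (adjusted p = 0.57, exact permutation p = 0.114). The log2 change over 12 h was -0.57 in the inducible line (adjusted p = 0.094) and 0.35 in wild type (adjusted p = 0.30), and their difference was -0.93 (SE 0.26, adjusted p = 0.14). With a lane term that difference had an adjusted p of 0.048, with the replicate block 0.059, and in DESeq2 0.038. The change in the inducible line had an adjusted p of 0.044 with a lane term and 0.052 with the replicate block. The call at 12 h was lost without inducible-line 12 h replicate 1 (adjusted p = 0.078), 3 (0.119) or 4 (0.108), without wild-type 12 h replicate 2 (0.141) or 3 (0.122), and without inducible-line 0 h replicate 1 (0.056), 2 (0.054), 3 (0.054) or 4 (0.054). It was also lost with no filter (0.058), in the compared groups alone (0.108), and in lane 1 (0.290) or lane 2 (0.106) alone.

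**Figure D1:**
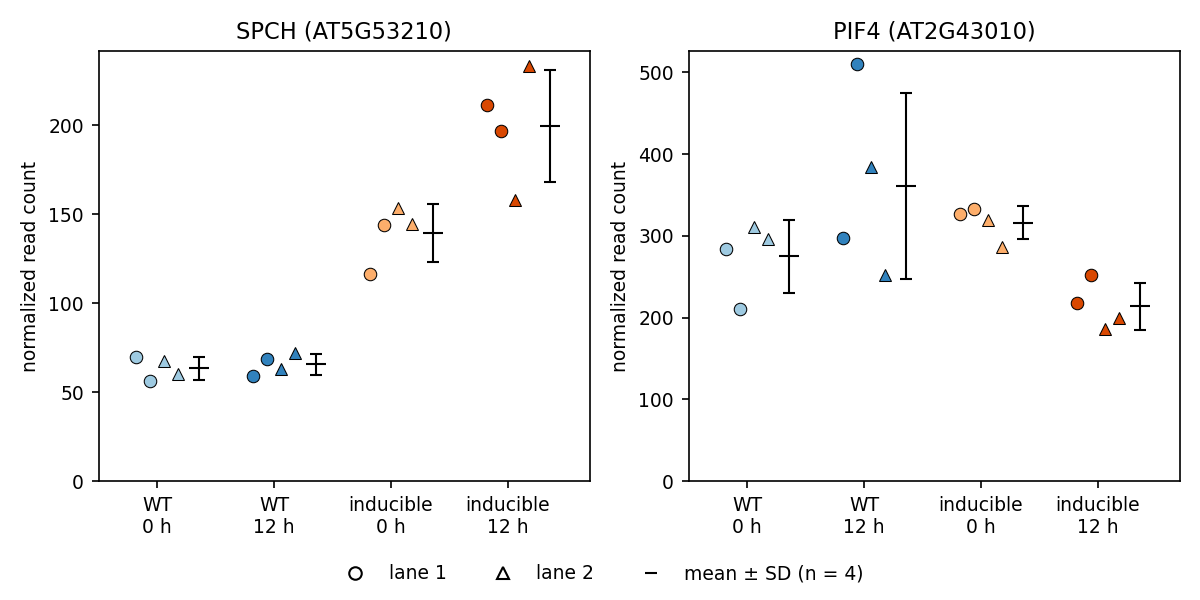
Normalized counts of SPCH and PIF4 in each library by line and time; circles are libraries of lane 1, triangles those of lane 2, and bars the mean ± SD of 4 libraries. SPCH averaged 140 and 200 in the inducible line and 63.4 and 65.7 in wild type.

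The line-by-time interaction asks which transcripts changed over 12 h of dexamethasone in the inducible line beyond their change in wild type, which received the same treatment. Of the stomatal lineage list 6 genes rose. EPF2 (AT1G34245, chromosome 1 from 12472868 to 12473974), a secreted peptide that restricts entry into the lineage, rose 8.65-fold beyond wild type (log2 3.11, SE 0.38, adjusted p = 8.0e-04), from 57.3 ± 18.6 to 479 ± 164 (SD, n = 4) against 66.2 ± 23.6 and 60.2 ± 4.78 in wild type. TMM (AT1G80080, chromosome 1 from 30127819 to 30129649), a receptor-like protein of the same signalling, rose 4.99-fold beyond wild type (2.32, SE 0.18, adjusted p = 8.6e-06). It went from 286 ± 21.4 to 1351 ± 106, against 256 ± 51.4 and 238 ± 10.8 in wild type. The division polarity genes BASL (2.42, SE 0.44, adjusted p = 0.017) and POLAR (1.82, SE 0.21, adjusted p = 2.8e-04) rose beyond wild type. So did ICE1 (1.07, SE 0.13, adjusted p = 0.0010) and SCRM2 (1.02, SE 0.17, adjusted p = 0.010), which encode binding partners of SPCH.

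Of the 18 measured members of the stomatal lineage list 6 rose, none fell and 12 did not pass, and 7 rose when adjusted over the list alone (9 with the replicate block). The list as a whole had a camera adjusted p of 1.1e-11, and an adjusted p = 0.0016 with an estimated correlation, or 0.027 with the replicate block as well. Among the 12 that did not pass were ERL1 (0.77, adjusted p = 0.27), BRXL2 (0.56, adjusted p = 0.36), SPCH (0.46, adjusted p = 0.43), MUTE (-0.59, adjusted p = 0.62), ERL2 (0.49, adjusted p = 0.66), FAMA (0.19, adjusted p = 0.77) and EPF1 (-0.38, adjusted p = 0.89). The calls of EPF2, TMM and CPL3 held in each lane alone. Those of BASL, POLAR, ICE1 and SCRM2 were lost in lane 1 alone, at adjusted p of 0.409, 0.133, 0.202 and 0.426. A fit of 1 lane holds 2 libraries per group, so a call lost there does not show that the change was absent. Of the genes called in the interaction 100% had the same sign in both lanes, though they were chosen over both lanes.

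**Figure D2:**
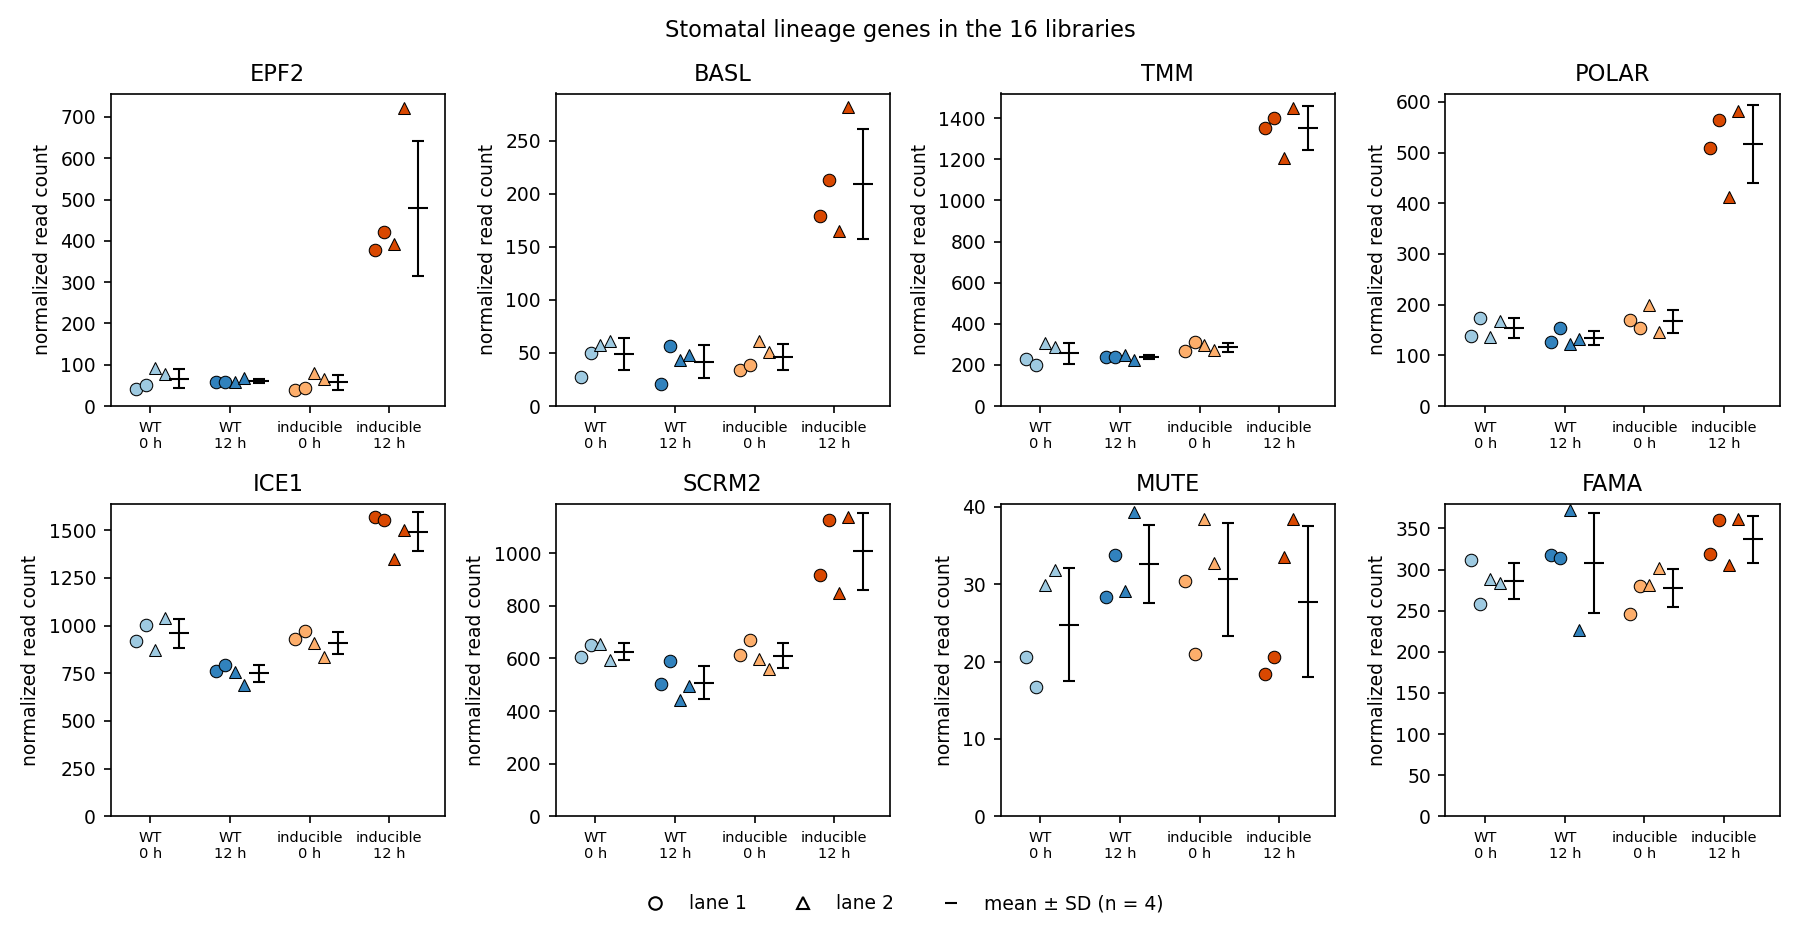
Normalized counts of stomatal lineage genes in each library by line and time; circles are libraries of lane 1, triangles those of lane 2, and bars the mean ± SD of 4 libraries. EPF2 averaged 57.3, 479, 66.2 and 60.2 in the inducible line at 0 h and 12 h and in wild type at 0 h and 12 h.

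Outside that list CPL3, also called ETC3 (AT4G01060), a small MYB protein that represses trichome and promotes root hair fate, rose 7.29-fold beyond wild type (log2 2.87, SE 0.24, adjusted p = 1.2e-05), from 55.8 ± 5.13 to 341 ± 52.2. Beyond wild type, AT3G14760 rose by 1.99 (SE 0.21, adjusted p = 1.4e-04), AT1G12845 by 1.58 (SE 0.20, adjusted p = 0.0011), AT5G11550 by 1.85 (SE 0.29, adjusted p = 0.0069) and AT5G10890 by 2.13 (SE 0.35, adjusted p = 0.011). Among the falls, thalianol synthase THAS1 (AT5G48010) had a log2 difference of -2.31 (SE 0.40, adjusted p = 0.015), from 1663 to 546 in the inducible line and from 1410 to 2120 in wild type. CYP708A2 (AT5G48000), which acts on thalianol, had -2.12 (SE 0.35, adjusted p = 0.011), and squalene monooxygenase SQP2 (AT5G24140) -2.05 (SE 0.34, adjusted p = 0.011). MSRB6 (AT4G04840), a methionine sulfoxide reductase, had -2.02 (SE 0.31, adjusted p = 0.0063). The lipid-transfer family gene AT5G46900 had -2.19 (SE 0.37, adjusted p = 0.011). Of the genes of this paragraph CPL3 kept its call in lane 1 alone, where the others had adjusted p from 0.175 (AT1G12845) to 0.451 (SQP2), and AT1G12845 and AT5G10890 also lost theirs in lane 2 alone.

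In the interaction 106 of 20756 genes passed, 20 higher and 86 lower. The replicate block gave 518 genes, 143 higher and 375 lower, the lane term 586 and DESeq2 378. Leaving out 1 library gave 53 to 454 genes, over 1.5 times off in 11 of 16 fits. Lane 1 alone gave 3 and lane 2 alone 117. The induction set, the genes that also differed between the lines at 12 h with the same sign, held 89 genes, 18 higher and 71 lower. It held 320 under the replicate block, 242 in DESeq2 and 48 to 220 without 1 library.

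Among the other lists, 1 of 26 mitotic genes rose in the interaction, the cyclin CYCB1;1 (1.05, SE 0.23, adjusted p = 0.049), a call that was lost in 14 of the 16 fits without 1 library. The mitotic list had a camera adjusted p of 1.2e-05, with 24 of 26 members higher, and adjusted p = 0.24 with an estimated correlation. Of 17 epidermis and cuticle genes 1 fell, the wax synthesis gene CER1 (-1.90, SE 0.41, adjusted p = 0.049, lost in 12 of those 16 fits), with a list adjusted p of 0.033 and adjusted p = 0.43 with an estimated correlation. Of 13 trichome genes 1 rose, ETC3, and the list had an adjusted p of 0.22. No member of the following lists passed over all genes. The jasmonate list (adjusted p = 1.4e-05, and adjusted p = 0.38 with an estimated correlation), the dark and sugar starvation list (adjusted p = 2.0e-04, and adjusted p = 0.081 with an estimated correlation) and the root hair list (adjusted p = 2.0e-04, and adjusted p = 0.28 with an estimated correlation) stood lower, with 1, 2 and 1 falls adjusted over the list alone. The auxin response list (adjusted p = 0.0011, and adjusted p = 0.13 with an estimated correlation), the defence list (adjusted p = 0.0038, and adjusted p = 0.25 with an estimated correlation) and the root endodermis list (adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation) stood lower too, with 0, 2 and 3 such falls. The call of the root endodermis list was lost with the replicate block (adjusted p = 0.14). The low-oxygen list (adjusted p = 0.026, and adjusted p = 0.46 with an estimated correlation) and the DNA replication list (adjusted p = 0.036, and adjusted p = 0.38 with an estimated correlation) stood higher. The replicate block put past the threshold 2 falls each of the defence, starvation and photosynthesis lists, and 1 each of the root hair and root endodermis lists. It did the same for 1 rise of the D-type cyclin list, and gave 2 falls and 1 rise of epidermis genes. Adjusted over the list alone it gave 3 jasmonate, 6 starvation, 2 root hair, 3 auxin and 5 defence falls. The list calls lost in lane 1 alone were those of epidermis (adjusted p = 0.166), root hair (0.188) and root endodermis (0.129). In lane 2 alone they were those of DNA replication (0.189), defence (0.065), low oxygen (0.912) and root endodermis (0.214). The remaining lists had adjusted p of 0.12 for D-type cyclins, 0.12 for photosynthesis, 0.21 for the circadian clock, 0.22 for brassinosteroid, 0.22 for PIF4 and warm temperature, 0.26 for vascular tissue, 0.31 for guard cells, 0.63 for seed storage with 1 measured gene, 0.74 for shoot meristem, 0.76 for abscisic acid and 0.88 for signalling upstream of SPCH.

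The change from 0 to 12 h in the inducible line asks what followed dexamethasone and the passing time together. EPF2 (log2 3.04, SE 0.27, adjusted p = 2.4e-06), CPL3 (2.58, SE 0.17, adjusted p = 9.4e-08) and TMM (2.24, SE 0.13, adjusted p = 2.1e-08) were among the largest rises. The defence protein gene PR5 rose by 2.33 (SE 0.31, adjusted p = 1.7e-04), from 270 to 1432, and AT2G04135 by 2.39 (SE 0.34, adjusted p = 3.1e-04). The largest falls were AT4G10265 of the wound-responsive family (-4.83, SE 0.41, adjusted p = 1.9e-06), from 695 to 27.6, and HRA1 (AT3G10040), a regulator of the low-oxygen response (-3.48, SE 0.24, adjusted p = 1.8e-07). HSPRO2 had -3.16 (SE 0.27, adjusted p = 2.4e-06), AT2G20670 -3.14 (SE 0.25, adjusted p = 9.5e-07) and AT3G23170 -3.10 (SE 0.25, adjusted p = 1.1e-06).

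Of the 18 stomatal lineage genes 6 rose in the inducible line, 9 adjusted over the list alone, with a list adjusted p = 0.0021 with an estimated correlation. Of 15 genes of darkness and sugar starvation 8 fell and 1 rose (9 fell and 1 rose adjusted over the list alone), among the falls EXL1 (-2.07, SE 0.25), KMD1 (-1.56, SE 0.23) and TPS8 (-1.51, SE 0.15), with a list adjusted p of 7.4e-08 and adjusted p = 0.0072 with an estimated correlation. Of 24 auxin response genes 1 fell, IAA1 (-0.76, SE 0.19), and 7 adjusted over the list alone, with a list adjusted p of 1.9e-07 and adjusted p = 0.0085 with an estimated correlation. No DNA replication gene passed, and all 18 had higher values (adjusted p = 9.1e-06, and adjusted p = 0.033 with an estimated correlation). With an estimated correlation and the replicate block together the calls of the starvation (adjusted p = 0.0592), auxin (0.0686) and DNA replication (0.155) lists were lost, and the stomatal lineage list had 0.031. Of 16 defence genes 6 fell, among them the regulators WRKY33 (-1.35, SE 0.17) and WRKY70 (-1.24, SE 0.18), and PR5 rose (adjusted p = 0.0047, and adjusted p = 0.17 with an estimated correlation). Of 12 low-oxygen genes 4 fell, among them LBD41 (-2.90, SE 0.31), and 2 rose, and the list had an adjusted p of 0.45. Of 17 epidermis genes 4 fell, CER1 by the most (-2.12, SE 0.29, list adjusted p = 3.8e-04, and adjusted p = 0.17 with an estimated correlation). Of 18 brassinosteroid genes 2 fell, BEE2 (-0.95, SE 0.15) and the cell wall enzyme TCH4 (-1.58, SE 0.24), with a list adjusted p of 0.0074 and adjusted p = 0.17 with an estimated correlation.

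In the same comparison 2 of 26 mitotic genes rose, CYCB1;1 (0.62) and CYCB1;2 (0.52), with a list adjusted p of 3.2e-05 and adjusted p = 0.17 with an estimated correlation. The clock genes RVE1 (-1.44, SE 0.18) and LHY (-0.48) fell and GI (0.48) rose of 20, and of 22 PIF4 and warm-temperature genes PIF5 fell (-0.75, SE 0.12) and HSP70 rose (1.04, SE 0.23). Of 18 jasmonate genes 2 fell (adjusted p = 0.0069, and adjusted p = 0.62 with an estimated correlation), of 23 photosynthesis genes 2 fell (adjusted p = 8.6e-04, and adjusted p = 0.39 with an estimated correlation), and of 14 root hair genes 1 fell (adjusted p = 8.6e-04, and adjusted p = 0.25 with an estimated correlation). Of 13 trichome genes 3 fell and 1 rose (adjusted p = 0.036, and adjusted p = 0.17 with an estimated correlation). With the replicate block 7 auxin genes fell (11 adjusted over the list alone), as did 7 epidermis, 6 trichome, 5 root hair and 4 photosynthesis genes. The block gave rises of 4 mitotic, 4 clock and 1 brassinosteroid genes, and 3 rises and 3 falls of the warm-temperature list. The list calls lost in lane 1 alone were those of jasmonate (adjusted p = 0.088) and trichome (0.084). In lane 2 alone they were those of defence (0.051), photosynthesis (0.196) and trichome (0.051). Altogether 1063 genes passed, 299 higher and 764 lower. The replicate block gave 1843, lane 1 alone 367 and lane 2 alone 748.

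The change from 0 to 12 h in wild type asks the same without the transgene. SBT3.3, a protease linked to immune priming, rose 9.32-fold (log2 3.22, SE 0.27, adjusted p = 3.5e-06), from 23.7 to 221, and PR5 rose 7.20-fold (2.85, SE 0.31, adjusted p = 8.5e-05), from 166 to 1177. The ankyrin-repeat gene ANK rose by 2.91 (SE 0.40, adjusted p = 4.9e-04) and PYD4 by 2.37 (SE 0.30, adjusted p = 2.3e-04). AT4G10265 (-4.61, SE 0.41, adjusted p = 1.1e-05), HRA1 (-3.49, SE 0.24, adjusted p = 8.4e-07) and the low-oxygen gene LBD41 (-3.24, SE 0.31, adjusted p = 3.6e-05) were among the largest falls.

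Of 18 stomatal lineage genes none rose and ICE1 fell in wild type (-0.35, adjusted p = 0.042, lost in 12 of the 16 fits without 1 library), and the list had an adjusted p of 0.37. Of 12 low-oxygen genes 4 fell and PDC2 rose (0.72), with a list adjusted p of 0.0052 and adjusted p = 0.77 with an estimated correlation, and 0.248 in lane 2 alone. Of 20 clock genes APRR7 (0.68), GI (0.56) and LNK1 (0.49) rose and RVE1 fell (-0.97, SE 0.18), with a list adjusted p of 0.38. Of 16 defence genes PR5 and FRK1 (1.44) rose and WRKY33 fell (-0.73), with 3 falls under the replicate block, and of 15 genes of darkness and sugar starvation DIN2 rose (1.49) while EXL1 (-1.37), KMD1 (-0.90) and TPS8 (-0.73) fell. Altogether 980 genes passed, 471 higher and 509 lower. The replicate block gave 2751, the lane term 3014, DESeq2 1788 and the compared groups alone 315. Leaving out wild-type 0 h replicate 1 gave 1889 and replicate 4 gave 476, the highest and lowest of those fits. Lane 1 alone gave 187 genes and lane 2 alone 1140.

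The 12 h changes of the lines, which share no library, were related across genes (Pearson r = 0.388, Spearman rho = 0.269, 58.8% of 20756 genes with the same sign). Genes are not independent replicates, and no p is given. Pearson r was 0.373 in lane 1 and 0.263 in lane 2. The lists of passing genes shared 118 rises and 187 falls where 6.78 and 18.7 would be shared by chance. Such chance values take the calls in the lines as independent. Both calls use 1 estimate of the spread per gene, so sharing by chance may be higher. Of the genes that passed in both lines, 3 had opposite signs. With the replicate block 259 rises and 346 falls were shared, where 39.3 and 85.4 would be by chance, and 27 genes passed with opposite signs. The 3 without the block were chosen after their values were seen: ICE1 rose in the inducible line (0.71) and fell in wild type (-0.35), while AT1G30700 of the berberine family (-0.56 and 0.75) and the sulfate transporter gene SULTR1;2 (-0.69 and 0.73) did the reverse.

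The comparison of lines at 12 h asks how the induced seedlings differed from treated wild type. CYP82C2, an enzyme of indolic defence metabolism, was 13.7-fold higher in the inducible line (log2 3.78, SE 0.35, adjusted p = 1.1e-05), at 824 against 58.4. The pyruvate decarboxylase gene PDC1 (AT4G33070, 3.28, SE 0.45, adjusted p = 7.7e-04), at 1744 against 149, and the alcohol dehydrogenase gene ADH1 (3.02, SE 0.44, adjusted p = 0.0010), at 1570 against 165, were higher. CPL3 was higher by 3.07 (SE 0.17, adjusted p = 1.8e-08) and the aquaporin gene NIP2;1 by 3.54 (SE 0.48, adjusted p = 3.8e-04). The lipid-transfer family genes AT5G46890 (-2.76, SE 0.21, adjusted p = 1.2e-06) and AT5G46900 (-2.76, SE 0.26, adjusted p = 1.1e-05), the methyltransferase family gene AT3G21950 (-2.39, SE 0.23, adjusted p = 1.1e-05) and MSRB6 (-2.28, SE 0.22, adjusted p = 1.1e-05) were lower. PDC1, ADH1 and NIP2;1 lost their calls in lane 2 alone, at adjusted p of 0.289, 0.245 and 0.069.

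Of the 18 stomatal lineage genes 9 were higher at 12 h, among them TMM (2.50, SE 0.13), ICE1 (0.99, SE 0.10) and SPCH, and 12 adjusted over the list alone, with a list adjusted p = 1.1e-04 with an estimated correlation. Of 12 low-oxygen genes 10 were higher, among them the sucrose synthase gene SUS4 (2.69, SE 0.47) and the haemoglobin gene HB1 (1.53, SE 0.32), and 11 adjusted over the list alone (list adjusted p = 8.3e-18, and adjusted p = 0.018 with an estimated correlation). Of 26 mitotic genes 5 were higher and 15 adjusted over the list alone, with CYCB1;1 at 0.74 (SE 0.16) and CDKB1;2 at 0.65 (SE 0.14), and 12 with the replicate block. All 26 had higher values (list adjusted p = 2.9e-14, and adjusted p = 0.018 with an estimated correlation). Of 24 auxin response genes 1 was lower, IAA19 (-1.41, SE 0.26), and 8 adjusted over the list alone (list adjusted p = 6.6e-07, and adjusted p = 0.018 with an estimated correlation). With an estimated correlation and the replicate block together the calls of the low-oxygen (adjusted p = 0.0649), mitotic (0.0649) and auxin (0.0650) lists were lost, and the stomatal lineage list had 0.0034. Of 22 PIF4 and warm-temperature genes 3 were lower, PIF4, HFR1 (-1.75, SE 0.35) and IAA19 (list adjusted p = 8.3e-05, and adjusted p = 0.062 with an estimated correlation).

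Of 17 epidermis and cuticle genes 5 were lower at 12 h, among them CER1 (-2.15, SE 0.29), KCS1 of very-long-chain fatty acid synthesis (-0.76, SE 0.11) and ATML1 (-0.57, SE 0.14), whose promoter drives the transgene, with a list adjusted p of 2.3e-07 and adjusted p = 0.062 with an estimated correlation. Of 13 trichome genes 3 were lower, GL2 (-1.05, SE 0.19), GL3 (-1.31) and TTG2 (-0.95), and 2 higher (adjusted p = 0.013, and adjusted p = 0.072 with an estimated correlation). Of 14 root hair genes 2 were lower, EXPA18 (-1.32, SE 0.26) and PHT1;1 (-0.85, SE 0.18), and 10 adjusted over the list alone (adjusted p = 1.9e-09, and adjusted p = 0.050 with an estimated correlation). Of 10 root endodermis genes 1 was lower, CASP2 (-0.94), and 6 adjusted over the list alone (adjusted p = 4.3e-04, and adjusted p = 0.072 with an estimated correlation). Of 23 photosynthesis genes 5 were lower, among them LHCA4 (-0.67) and LHCB3 (-0.60), with a list adjusted p of 2.1e-09 and adjusted p = 0.072 with an estimated correlation. The clock list stood lower, with LNK1 past the threshold (-0.43, list adjusted p = 8.0e-04, and adjusted p = 0.062 with an estimated correlation). The DNA replication list stood higher with no gene past it (adjusted p = 0.0058, and adjusted p = 0.11 with an estimated correlation). Of 16 defence genes PAD3 (1.42, SE 0.29) and WRKY33 (0.66) were higher (adjusted p = 0.036, and adjusted p = 0.23 with an estimated correlation), and of 14 genes of signalling upstream of SPCH MKK7 was higher (1.24, SE 0.28, list adjusted p = 0.036, and adjusted p = 0.14 with an estimated correlation). Of 15 abscisic acid genes COR47 (-0.80, SE 0.12) and RD22 (-0.86, SE 0.15) were lower (adjusted p = 0.036, 0.057 with the replicate block, and adjusted p = 0.20 with an estimated correlation), and of 18 brassinosteroid genes BEE2 was lower (-0.72, SE 0.15, list adjusted p = 0.047, and adjusted p = 0.20 with an estimated correlation). With the replicate block 6 auxin, 4 root hair, 2 clock and 2 brassinosteroid genes and 1 defence gene were lower and 2 genes of signalling upstream of SPCH higher. The list calls lost in lane 1 alone were those of signalling upstream of SPCH (adjusted p = 0.273), brassinosteroid (0.0999), abscisic acid (0.0987) and defence (0.121). In lane 2 alone they were those of brassinosteroid (0.055) and abscisic acid (0.0968). Altogether 706 genes passed, 250 higher and 456 lower. The replicate block gave 1332, DESeq2 1120, leaving out 1 library 428 to 800, and lanes 1 and 2 alone 175 and 437.

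**Figure D3:**
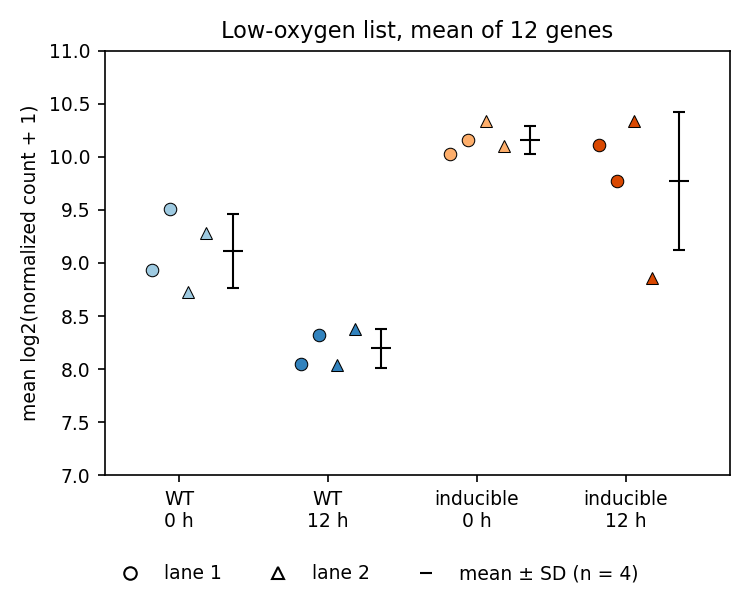
Mean log2 level of the 12 measured low-oxygen genes in each library by line and time; circles are libraries of lane 1, triangles those of lane 2, and bars the mean ± SD of 4 libraries. The inducible line spanned 10.03 to 10.34 at 0 h and 8.86 to 10.33 at 12 h, and wild type 8.72 to 9.51 and 8.03 to 8.38.

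The comparison of lines at 0 h asks how the transgenic line differed before dexamethasone was added. CYP82C2 was 18.3-fold higher on average (SE 0.35 on the log2 scale, adjusted p = 3.0e-05), at 334 against 15.8. NIP2;1 was higher by 2.90 on that scale (SE 0.48, adjusted p = 0.0069), PDC1 by 2.42 (SE 0.45, adjusted p = 0.016) and CYP71A12, an enzyme of indolic defence metabolism, by 2.47 (SE 0.45, adjusted p = 0.013). The lipase gene GLIP1 was higher by 2.87 (SE 0.54, adjusted p = 0.012). The falls were smaller, with AT1G11700 at -1.22 (SE 0.23, adjusted p = 0.013) and the chloroplast gene ATCG00400 at -1.01 (SE 0.20, adjusted p = 0.014). Of these 7 genes, CYP82C2 kept its call in lane 1 alone and the others did not, and PDC1 also lost its call in lane 2 alone (adjusted p = 0.151). Leaving out inducible-line 0 h replicate 1 ended the call of GLIP1 (adjusted p = 0.05), leaving out replicate 3 that of PDC1 (0.059), and leaving out replicate 4 those of PDC1 (0.05), CYP71A12 (0.052) and AT1G11700 (0.051).

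Of 18 jasmonate and wound genes 3 were higher at 0 h, JAZ2 (0.76, SE 0.12), JAZ7 (1.59) and JAZ8 (2.47), and 8 adjusted over the list alone, with all 18 values higher (list adjusted p = 7.2e-09, and adjusted p = 0.44 with an estimated correlation). Of 16 defence genes 5 were higher, among them WRKY33 (1.29, SE 0.17) and WRKY70 (1.21, SE 0.18), and 8 adjusted over the list alone (list adjusted p = 3.6e-07, and adjusted p = 0.084 with an estimated correlation, or 0.043 with the replicate block as well). Of 12 low-oxygen genes 3 were higher, PDC1, PCO2 (1.62) and HRA1 (1.05), and 9 adjusted over the list alone, with 6 past the threshold with the replicate block (list adjusted p = 7.2e-09, and adjusted p = 0.19 with an estimated correlation). Of 15 genes of darkness and sugar starvation 2 were higher, DIN2 (1.59) and TPS8 (0.65), with a list adjusted p of 2.6e-04 and adjusted p = 0.084 with an estimated correlation. Of 23 photosynthesis genes 1 was lower (adjusted p = 0.0014, and adjusted p = 0.46 with an estimated correlation), and the direction of that list was reversed in lane 1 alone (adjusted p = 0.790). Of 17 epidermis genes 1 was lower, KCS1 (adjusted p = 0.047, adjusted p = 0.46 with an estimated correlation, and 0.296 in lane 2 alone). With the replicate block 5 jasmonate, 4 starvation and 2 stomatal lineage genes were higher and 5 photosynthesis and 4 epidermis genes lower. Of the 18 stomatal lineage genes SPCH was higher, and the list had an adjusted p of 0.17. Altogether 414 genes passed, 295 higher and 119 lower. The replicate block gave 2351, 1218 higher and 1133 lower, the lane term 2641, DESeq2 1360 and the compared groups alone 138. Leaving out wild-type 0 h replicate 1 gave 1803 and inducible-line 0 h replicate 4 gave 120, the highest and lowest of those fits. Lane 1 alone gave 1 gene, and lane 2 alone gave 1846, 954 higher and 892 lower.

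The libraries separated by lane along the first principal component, which held 49.5% of the variance, and 8187 of 20756 genes differed between the lanes, 4099 higher and 4088 lower in lane 2. Each lane held 2 libraries of every group.

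**Figure D4:**
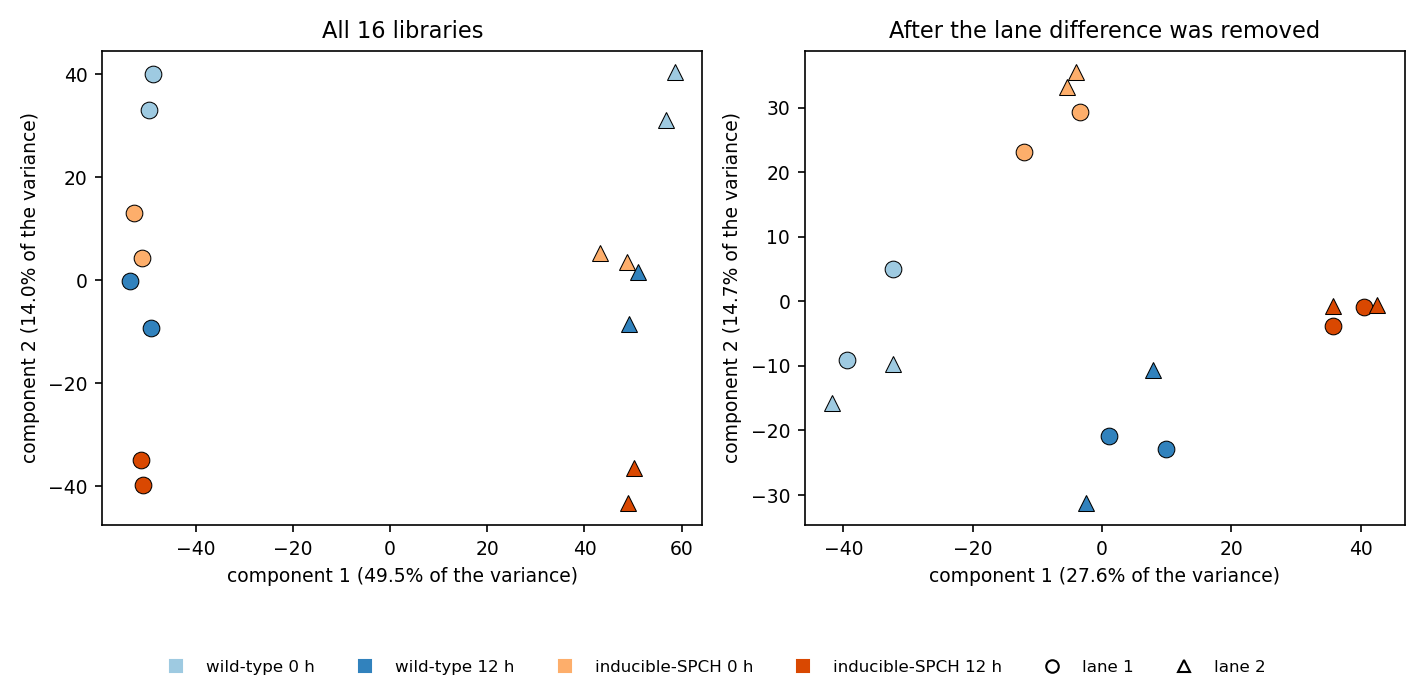
Principal components of log2 normalized counts for the 16 libraries, before (left) and after (right) subtraction of the lane difference, with the percent of variance on each axis. The first component held 49.5% before and 27.6% after.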

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

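The test of a group difference by the interaction and the splits of the libraries were planned. So were the correlations of the lane difference with GC content and with exon length. The other tests here, with their limits, were chosen after the result was seen.

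Single libraries stood apart from the other 3 of their group in 15 of 236 groups over 59 measures, by a share of the group's range above Dixon's 95% critical value, and chance gives about 11.8 of the 236; these shares are in parentheses. By list level these were wild-type 0 h replicate 2 for mitotic genes (0.927) and the single seed storage gene (0.861), inducible-line 0 h replicate 3 for DNA replication (0.853), wild-type 12 h replicate 2 for abscisic acid genes (0.871) and inducible-line 12 h replicate 2 for root hair genes (0.898). EPF2 stood apart in inducible-line 12 h replicate 4 (0.877), at 723 against 379 to 421, and in wild-type 12 h replicate 4 (0.897). In inducible-line 12 h replicate 1, THAS1 was at 1006 against 322 to 436 (0.833) and CYP708A2 at 981 against 414 to 463 (0.912). The others were AT5G11550 in wild-type 0 h replicate 1 (0.863), MSRB6 in inducible-line 0 h replicate 1 (0.848) and 12 h replicate 4 (0.874), MYB88 in inducible-line 12 h replicate 2 (0.847), and TCX2 in wild-type 0 h replicate 3 (0.938) and 12 h replicate 3 (0.926).

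The 12 h change differed between the lines by the interaction test in 106 genes. Of 100 splits of the libraries 3, the real one included, gave as many genes, and the highest other split gave 4228. That split placed the lanes unequally between the groups, which points to the lanes as a structure of the samples. With the lane term, where every split was balanced over lanes, 2 of 100 gave as many as the real 586, the highest other at 826. For the induction set 3 of 100 gave as many as 89, the highest other at 1205. The splits moved the line labels within each time, so they also carried any difference between the lines common to both times. They ask whether the lines differed at all, and do not exclude chance for the interaction alone. Opposite changes in the lines with an interaction past the threshold were found in AT1G30700 (-1.30, SE 0.21, adjusted p = 0.010), SULTR1;2 (-1.42, SE 0.27, adjusted p = 0.023) and ICE1 (1.07, SE 0.13, adjusted p = 0.0010).

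For the change in the inducible line, 1 of 35 splits gave as many as the real 1063 genes, and the highest other gave 0. For the lines at 12 h 1 of 35 did, at 706 against 1, and for the lines at 0 h 1 of 35, at 414 against 283. In these 3 the real split gave the most genes, and 1 of 35 is the smallest share possible. This argues against a random parting of these libraries, without adjustment over the comparisons. Chance differences between cultures, which the labels do not give, are not covered. For the change in wild type 2 of 35 splits gave as many as the real 980, and chance cannot be excluded from this count alone. The other one, with 2573 genes, followed the lanes, and the highest that did not gave 894. With the replicate block the real split gave 2751, and the highest of the others that part the libraries of every replicate number gave 4. These 8 splits are too few for a share under 0.05.

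Between the lanes 328 genes differed by over 2 on the log2 scale, such as F3H at 1760 against 0.598 and UBQ6 at 7928 against 0.133 in lanes 1 and 2. Of these 66.5%, F3H among them, were covered for 25% or more of their length by a gene on the opposite strand, against 3.07% of the other genes (Fisher's exact test, p = 1.3e-228), so reads of overlapping genes may have been assigned differently in the lanes. Of all genes that differed 7.01% were so covered, and UBQ6, with the largest difference, was not, which argues against this as the whole cause. Across genes without such cover, the lane difference had a rho of -0.076 with GC content, which argues against GC content. Its rho with exon length was -0.358, past the size set beforehand for exon length as an explanation. Exon length may therefore account for a part, and what lies behind the remaining differences stays open. No biological explanation was tested. Each lane held all groups, so line and time do not account for the difference. The labels do not say whether the libraries of the lanes came from separate cultures. A difference between cultures therefore cannot be told apart from the lane.

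The 86 genes that fell in the interaction had a median of -1.53 on the log2 scale. The 24 measured root hair and root endodermis genes had a median of -0.47 (quartiles -0.86 and -0.36), against -0.0025 over all tested genes. The smaller size in the root genes does not decide about a smaller root share of the seedlings. The 86 genes were chosen for passing the threshold in this same comparison, and the root genes were not. The medians of the 86 genes in the lanes, -1.41 and -1.67, decide nothing about the lane difference, because these genes were chosen over both lanes. The 89 genes that fell in lane 2 alone had a median of -1.61 there and of -1.04 in lane 1 (quartiles -1.43 and -0.62), which argues against the lane difference as the whole cause. Of the 86 fallen genes 0 were covered by a gene on the opposite strand. An effect of the SPCH fusion, as the design names it, stays open, and so do a smaller root share and other cell types that the lists do not hold.

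The 12 low-oxygen genes were higher in the inducible line at 12 h by a median of 1.34, with 1.65 and 1.03 in the lanes, which argues against the lane difference. At 0 h the median was 1.04, or 77.7% of that at 12 h (2-sided exact permutation p = 0.0286 at both times, the smallest possible), which argues against nuclear entry of the fusion after dexamethasone as the whole cause. All 12 were higher at both times, and the oxygen supply of separate cultures cannot be told apart from the line, because the labels do not give the cultures. A difference between the lines themselves stays open, possibly together with it.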

How the results depend on the processing

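Alternatives with edgeR and TMM factors, the replicate block on edgeR, other pseudocounts, TMM factors under limma, lists in each lane alone, and the omission of genes covered by a gene on the opposite strand were chosen after seeing the data. The counts of genes in the order interaction, inducible line over time, wild type over time, lines at 12 h, lines at 0 h and induction set moved by over 1.5 times as follows. The lane term gave 586, 1921, 3014, 1414, 2641 and 341, the replicate block 518, 1843, 2751, 1332, 2351 and 320, edgeR with the block 529, 1839, 2759, 1319, 2371 and 321, and omission of covered genes with the block 519, 1788, 2689, 1316, 2275 and 319. These settings remove the lane difference from the error. Lane 1 alone gave 3, 367, 187, 175, 1 and 3, and the cause was not tested. DESeq2 gave 378 in the interaction, 1788 in wild type, 1120 and 1360 for the lines at 12 h and 0 h and 242 in the set, and the cause was not tested. Lane 2 alone gave 437 for the lines at 12 h and 1846 at 0 h. The compared groups alone gave 315 in wild type and 138 for the lines at 0 h. The stricter adjusted p of 0.01 gave 19, 537, 288, 298 and 83, and a log2 size of at least 1 gave 493, 265, 360 and 156 after the interaction. PIF4 in the interaction passed in DESeq2 (0.0382) and with the lane term (0.0483). The photosynthesis list at 0 h reversed in lane 1 alone (adjusted p = 0.790).

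Leaving out 1 library gave 53 to 454 genes in the interaction, 746 to 1175 in the inducible line, 476 to 1889 in wild type, 428 to 800 for the lines at 12 h, 120 to 1803 at 0 h, 48 to 220 in the set, and an adjusted p of 0.0903 to 0.257 for PIF4. Without wild-type 0 h replicate 1 the counts rose to 454, 1889, 1803 and 220. In the interaction the count fell without inducible-line 0 h replicates 1 (64), 2 (66) and 4 (56), 12 h replicates 2 (59) and 3 (53), wild-type 0 h replicates 3 (63) and 4 (64), and 12 h replicates 1 (70), 2 (57) and 4 (59). In wild type it fell without 0 h replicates 3 (618) and 4 (476) and 12 h replicates 1 (515), 2 (523) and 4 (585). For the lines at 12 h it fell without inducible-line replicate 2 (453) and wild-type replicates 2 (428) and 3 (462), and at 0 h without inducible-line replicates 1 (149), 3 (129) and 4 (120) and wild-type replicates 3 (155) and 4 (151). Of 192 calls of named genes none reversed, the block, the lane term and DESeq2 lost 0 and gained 93, 100 and 65 of about 360 others, no filter lost 17, limma-voom 14, single left-out libraries 0 to 40, lane 1 alone 115 and lane 2 alone 81. Of 46 list calls an estimated correlation kept 9, fry 26, the block 44, the block with an estimated correlation 4, TMM factors 46, lane 1 alone 36 with 1 reversed, lane 2 alone 35, and fits without 1 library 40 to 45. Those fits ended list calls, with their number, in the interaction for root endodermis (10), DNA replication (7), low oxygen (4), epidermis (4) and defence (1), in the inducible line for trichome (3) and jasmonate (2), and in wild type for low oxygen (1). For the lines at 12 h they ended brassinosteroid (7), abscisic acid (5), defence (4) and signalling upstream of SPCH (4), and at 0 h epidermis (6) and photosynthesis (1). Other calls printed in the report that were lost in some of the 16 fits without 1 library, with the number of those fits, were as follows. For the inducible line CYCB1;1 (6), CYCB1;2 (6), LHY (7), IAA1 (4). For wild type WRKY33 (2), FRK1 (6), PDC2 (6), KMD1 (5). For the lines at 12 h MKK7 (3), CYCB1;1 (1), CDKB1;2 (2), LNK1 (1), WRKY33 (8), LHCB3 (5), LHCA4 (5), ATML1 (5), GL3 (5), TTG2 (4), PHT1;1 (1), CASP2 (6). For the lines at 0 h PDC1 (2), GLIP1 (1), CYP71A12 (1), AT1G11700 (1), JAZ7 (5), JAZ8 (7), PCO2 (6), HRA1 (7), DIN2 (2), TPS8 (5), KCS1 (10). The block ended no call of a named gene and 2 list calls, root endodermis in the interaction and abscisic acid for the lines at 12 h. The alternatives not named here left each of the 6 counts within 1.5 times its main value.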

Other observations

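All tests here were chosen after the result was seen.

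Of 20 clock genes in wild type none changed by 2 or more on the log2 scale between 0 and 12 h, the largest being RVE1 at -0.97, and its size with 2 standard errors added was 1.33. This argues against opposite clock phases at 0 and 12 h only if the seedlings kept strong rhythms in step. That was not tested, and the labels give no time of day. In the inducible line RVE1 had -1.44.

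The 86 genes that fell in the interaction held 15 pairs within 2 tested genes of each other, where random sets matched on expression held a median of 1 and at most 6 (10000 sets, permutation p = 1e-04, the smallest they can give). THAS1 and CYP708A2 formed such a pair, as did AT5G46890 and AT5G46900. Falls may therefore lie beside each other in the genome more often than matched genes do. In 5 of the 15 pairs both genes had the same product name, and reads shared between duplicates could add to these. NSP1 and NSP4, both nitrile specifier proteins, are not among these 5. Some genes entered several pairs, so the pairs are not separate places. AT1G30700, AT1G30720 and AT1G30730 did so, as did NSP1, NSP4, PBP1 and JAL31, named after their values were seen. The random sets were matched on expression alone and did not keep neighbouring duplicates together.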
